A study of Pogonatum aloides with 7 samples.

How the data were processed

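Whole transcriptomes of Pogonatum aloides were sequenced, per the labels on an Illumina HiSeq platform from total RNA extracted with TRIzol. The deposited values analysed here were 6 tables, 1 per library, for capsule stages 1 to 5 and the young gametophyte. A seventh sample, a pool of capsules and gametophytes, was not analysed here. Per the file headers, the authors' values are RPKM, reads scaled to unigene length and library total, for 74566 unigenes of an assembly whose name in the identifiers joins seedlings and capsules. A dash stands where no value is listed and was read as 0. The assembler, the aligner and the counting rule are not given in the sources used here, and neither is the treatment of reads that match several contigs. What a shared cluster number means is not given there either; where such contigs are similar, the authors' counting could split reads between them, and values of single contigs are uncertain to that extent. The highest contig numbers of the clusters sum to 29345 against 21844 contigs listed, and the highest number of a single unigene was 56612 against 52722 listed, so the files hold part of the numbered entries. Every unigene was listed in at least 1 library. No reference genome, annotation or table of gene names was used, and 0 identifiers could be paired with a gene. Functional lists fixed beforehand (photosynthesis, cell division, meiosis, spore wall, storage and desiccation, stomata, sporophyte regulators, cuticle, auxin, cell wall and other organisms) were therefore not applied.

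Depth was worked back from the values, and the reads are called recovered reads in the text. An RPKM is the reads divided by the product of unigene length and library total, so repeated low values within a library fall on steps set by whole lengths. The total of each library was estimated from these steps, and for each unigene the smallest whole length between 200 and 15000 bases was found at which all its listed values are whole reads, within 0.9 of the last digit printed. Lengths were found for all 74566 unigenes (100.0%). The reads summed to between 99.4% and 99.7% of the implied totals of the capsule libraries and to 96.1% of that of the gametophyte. A doubled gametophyte total also gave whole reads for all unigenes, as any multiple does, and the smaller total was taken. If it were double, about every other unigene would need a doubled length, which makes its reads even in all capsule libraries. This held for 2.35% of the 13278 unigenes read in every library with at least 20 reads in one of them. On simulated reads it held for 54.8% of 13889 unigenes with a doubled total and for 2.32% of 12595 with the total as taken. Recovered lengths were odd for 49.7% of the 13278, where doubling all totals would leave few odd. Both mates of a pair counted as separate reads were not tested for. Where all reads of a unigene share a common factor with its length, its reads and length can be underestimated. A unigene listed in 1 library rests on 1 value and is most exposed to this. On simulated reads for 72939 unigenes, 94.6% were recovered exactly in length and reads. With at least 20 reads in one library, reads were exact for 93.2%. The simulation started from the recovered lengths, already the smallest that fit, so these rates can be too favourable. Its lowest library recovered 97.7% of its total, against 96.1% for the real gametophyte. Implied totals were 5751812, 5752394, 5747499, 5458335 and 5729201 for stages 1 to 5 and 3821669 for the gametophyte. The lowest listed value in each library corresponded to 1 read at these totals. No pair of libraries held identical values.

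The design was fixed before the data were examined, for files with counts or, as found, with RPKM only. The main tests used limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(RPKM + 1), for unigenes with at least 1 RPKM in one library of the fit, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes on this scale understate the change of low unigenes. The minimum of 1 RPKM was not in the design for RPKM and took the place of a count filter. Comparisons were the 5 capsules against the gametophyte, the slope per stage (stages taken as equally spaced), and the big and the middle-sized capsules against the 3 small stages. No label says that the small stages are replicates, and p-values measure only the spread between these single libraries. A unigene with no read in any library of a group has no spread there, so that such unigenes pass the test easily. Pairs of single libraries were compared without a test, by a ratio of RPKM + 1 of at least 2 with at least 1 RPKM in either library. Unigenes were called restricted to a library at 2 RPKM or more with no read elsewhere. Exact conditional-binomial 95% intervals of read ratios, and a minimum of 20 reads for restricted unigenes, had been planned for files with counts and were added once reads had been recovered.

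In simulations with the spread of the real capsules over 45992 unigenes, the capsule and gametophyte test recovered 15% of unigenes changed by 4 log2 units and 43% of those changed by 8, with 9 false calls. The stage slope test, over 44527 simulated unigenes, recovered 0% of 100 unigenes at 1 log2 unit per stage and 32.7% of 98 at 2, with 0 false calls. Both simulations drew the libraries independently, capped the spread, and planted changes only in a middle range of read numbers. They left out unigenes with no capsule read, a class that made up 16646 of the 18327 lower calls against the gametophyte. The 9 false calls therefore do not bear on that class. Counting intervals called 1.15% of unigenes above 2-fold at a true ratio of 2. In the test of contigs within clusters, 60 planted replacements gave 80 clusters against at most 46 in 100 shuffles, and none planted gave 21 against at most 36.

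The unigenes named in the text were chosen by a rule fixed beforehand for identifiers without gene names: the largest rise and fall of the capsule and gametophyte test among unigenes past 0.05, with a mean of at least 5 RPKM, at least 1 read in every library and all capsules on one side of the gametophyte, and the largest rise and fall over the stages. As no unigene passed the stage test, the latter were taken by the counting bound of the ratio of stage 5 to stage 1 among unigenes that moved one way at every step.

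Alternatives were TMM and median-ratio scaling (written out in Python 3.11.15 with numpy 2.4.6, trimming 30% of log ratios and 5% of levels), no filter, at least 50 recovered reads, a pseudocount of 0.1, other thresholds, and leaving out each stage. Added after seeing the data were tests on unigenes read in every library of the fit, limma-voom on recovered reads, counting intervals and the comparison of contigs within clusters. Count models planned for files with counts were not run, because the files hold RPKM. No paired analysis was possible because each group had 1 library.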

Results

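The transcriptome of the moss Pogonatum aloides was measured by RNA sequencing in capsules of 5 developmental stages and in young gametophytes. The capsule is the spore-bearing organ of the diploid sporophyte, and the gametophyte is the haploid leafy plant on which the sporophyte grows. The labels describe the capsules of stages 1, 2 and 3 as small, those of stage 4 as middle-sized and those of stage 5 as big, and the gametophytes as seedlings. The series names the young gametophyte as the control for the capsules. Each stage and the gametophyte had 1 library, so no group had a replicate, and a further pooled sample was not analysed here. Expression was given as RPKM for 74566 unigenes, which are sequences assembled from RNA reads without a genome. Of these, 21844 were contigs numbered within 11558 clusters and 52722 were single unigenes. The identifiers carry no gene names, so groups of unigenes are described here by their expression profile and not by function.

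The steps between low RPKM values implied library totals of 5751812, 5752394, 5747499, 5458335 and 5729201 reads for capsule stages 1 to 5 and 3821669 reads for the gametophyte. By these totals the gametophyte library was the shallowest. At these depths 3 reads on a 1 kb unigene correspond to 0.52 RPKM in stage 1 and 0.785 RPKM in the gametophyte. Intervals computed from these reads cover counting error only, since a stage had no second library.

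More unigenes were read in the gametophyte than in any capsule library. With every library thinned to 3674086 reads, 46680 unigenes were detected in the gametophyte and between 36482 (stage 4) and 39943 (stage 5) in the capsules. At full depth the unigenes detected in the gametophyte were shorter, with a median recovered length of 448 bases against 532 to 572 bases in the capsules. Unigenes listed in 1 library only numbered 17075 in the gametophyte and 491 to 1637 in a capsule library. Their lengths rest on 1 value and can be underestimated. The contrast in length and the cut at 500 bases are uncertain to that extent. Among unigenes of at least 500 bases the numbers lay close together, at 21713 in the gametophyte and 20409 to 21620 in the capsules. The 100 most abundant unigenes held 14.9% of the summed RPKM in stage 5, 23.5% in stage 3 and 20.3% in the gametophyte.

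The first comparison asked which transcripts distinguish the capsule from the young gametophyte. Each side held many unigenes that were not read on the other. There were 17075 unigenes read in the gametophyte and in none of the 5 capsule libraries. They held 15.2% of its reads as recovered, a share that can be underestimated. Of these, 324 reached 100 RPKM in the gametophyte. The most abundant, a unigene of 3121 bases, stood at 4254 RPKM with 50741 reads in the gametophyte and had 0 reads in each capsule library. Against the limit that 0 reads allow (3 reads per library), it was at least 24157-fold higher in the gametophyte than in stage 4, the capsule library with the least strict limit. With the same minimum for both sides (at least 2 RPKM and no read on the other side), 15424 unigenes were read in the gametophyte and no capsule library. For any of the 5 capsule libraries and not the gametophyte the number was 17225. At 20 reads these numbers were 4283 and 4870, and at 50 reads 1945 and 1993. The sides are not like for like. Gametophyte unigenes had to be unread in all 5 capsule libraries, each deeper by the implied totals. Capsule unigenes could come from any of the 5 and had to be unread only in the shallower gametophyte library. The closeness of the numbers therefore does not show that both organs hold similar numbers of such unigenes. With at least 2 RPKM in every capsule library and no gametophyte read there were 542. With any read in every capsule library and none in the gametophyte there were 5201, which held 3.07% of the capsule reads, and 77 of them reached 100 RPKM in at least one capsule library.

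Of 66294 unigenes with at least 1 RPKM in one library, 1662 were higher and 18327 lower in the capsules at an adjusted p under 0.05 (limma on log2(RPKM + 1), Benjamini-Hochberg adjustment). The spread in this test is that between the 5 capsule stages, and the lone gametophyte library is assumed to vary as they do. Among the lower calls, 16646 had no read in any capsule library, where the values of the 5 stages do not vary. Such unigenes pass whatever their number of reads. Without the 1 RPKM filter, all 17075 unigenes read in the gametophyte only were called lower. Of the 17075, 4283 had at least 20 gametophyte reads. Among the higher calls, 617 had no read in the gametophyte. When only the 17586 unigenes read in every library were tested, a restriction chosen after seeing the data, limma called 159 higher and 174 lower. The split between directions turned with limma-voom on the recovered reads, also chosen after seeing the data, which called 938 higher, each with no gametophyte read, and 82 lower. Of these 82, 2 had no read in any capsule library. All 5 capsule values lay above the gametophyte value for 16.9% of the tested unigenes and all lay below it for 34.8%. Exchangeable libraries without ties would give 16.7% each. A unigene unread in the gametophyte and in a capsule library cannot count as above. The share expected above is therefore lower than 16.7%, and the 16.9% is not shown to match it. The median unigene was 0.24 higher in the capsules on this log2 scale, a shift that was 0.05 after TMM scaling and −0.10 after median-ratio scaling.

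The largest rise among unigenes read in every library was that of CL3401.Contig3, a contig of 1053 bases. It was the most abundant unigene of capsule stages 1, 2, 3 and 5. Its level was 13413 ± 8531 RPKM in the capsules (SD, n = 5 stages), from 4757 in stage 5 to 25725 in stage 3, against 1.24 RPKM (5 reads) in the gametophyte. The log2 fold change was 12.28 with a standard error of 1.04 and a limma adjusted p of 0.000597. The ratio of pooled capsule reads to gametophyte reads was 10857, with a 95% exact counting interval from 4652 to 33436. When limma-voom was applied to the recovered reads, the log2 fold change was 13.00 with a standard error of 5.81 and an adjusted p of 0.513, so this call was lost there, while the other alternatives gave adjusted p-values from 0.000375 to 0.00410. The largest fall was that of Unigene16914, of 211 bases, at 4.13 ± 4.43 RPKM in the capsules (SD, n = 5 stages) and 1272 RPKM (1026 reads) in the gametophyte. Its log2 fold change was −8.33 with a standard error of 1.16 and a limma adjusted p of 0.00481, and its reads were 305-fold lower in the capsules, with a 95% exact counting interval from 206 to 474.

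**Figure D1:**
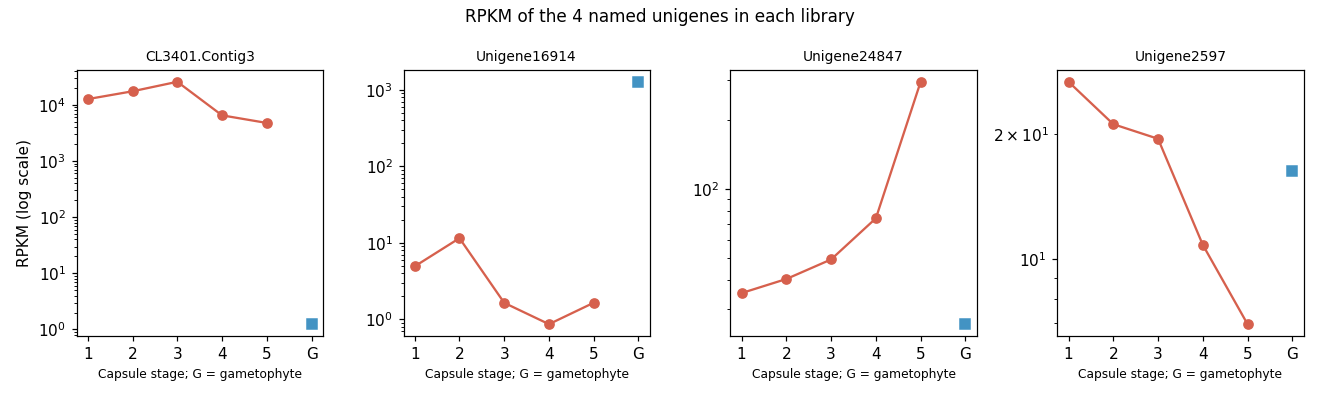
RPKM (log scale) of the 4 unigenes named by a fixed rule in the capsule libraries of stages 1 to 5 (circles) and the young gametophyte (square, G), 1 library each. CL3401.Contig3 lies between 4757 and 25725 RPKM in the capsule libraries and at 1.24 RPKM in the gametophyte, and Unigene16914 stands at 1272 RPKM in the gametophyte.

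Each capsule stage was then set against the gametophyte. With 1 library on each side no test was possible, and the counts describe these libraries. More unigenes were lower than higher by at least 2-fold in RPKM + 1 at every stage. The numbers higher were 16154, 14996, 14217, 15162 and 18712 for stages 1 to 5, and the numbers lower were 22324, 24387, 21941, 25360 and 24652. Between 72.3% (stage 3) and 80.2% (stage 5) of the unigenes with at least 1 RPKM in either library changed by this measure. Fewer passed when counting error was allowed for. The 95% exact counting interval lay wholly beyond 2-fold for 5330, 5012, 4387, 5998 and 6992 higher and for 12716, 13402, 12348, 13885 and 13940 lower unigenes at stages 1 to 5. All 5 comparisons share the same gametophyte library, so they are not independent of each other. The 15424 unigenes of at least 2 RPKM in the gametophyte and no capsule read recur in all 5 lower counts by the ratio. A single read also gives a higher RPKM in the shallower gametophyte library, so the ratio does not treat both sides alike.

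**Figure D2:**
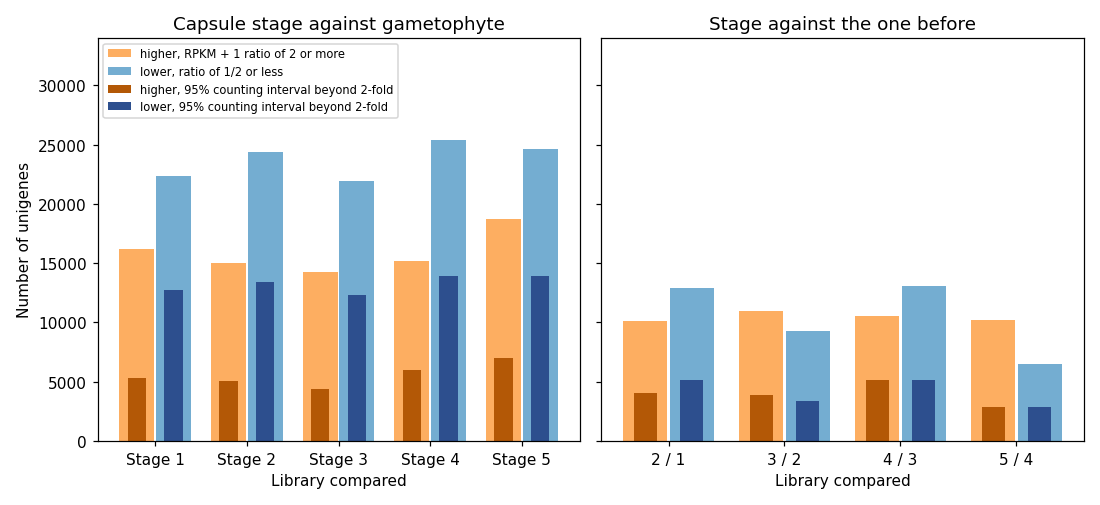
Number of unigenes higher or lower in each capsule stage against the gametophyte (left) and in each stage against the one before (right). Pale bars count ratios of RPKM + 1 of at least 2-fold and dark bars count 95% exact counting intervals wholly beyond 2-fold; lower unigenes outnumber higher ones at every stage against the gametophyte.

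The capsule libraries did not resemble each other in the order of their stages. Across 66294 unigenes, stages 1 and 3 were the most alike, with a Spearman rho of 0.83, followed by stages 2 and 5 at 0.79, stages 2 and 4 at 0.74 and stages 4 and 5 at 0.71. Of the neighbouring stages, 4 and 5 were thus among the more similar pairs, while rho was 0.57 for stages 1 and 2, 0.61 for stages 2 and 3 and 0.51 for stages 3 and 4. The remaining pairs lay at 0.60 (stages 1 and 5), 0.57 (stages 3 and 5) and 0.48 (stages 1 and 4). The gametophyte had a rho between −0.07 (stage 5) and 0.10 (stage 3) with the capsules. Unigenes read in the gametophyte only enter this rho and are tied at 0 in every capsule library. Pearson r of log2(RPKM + 1) was 0.25 (stage 5) to 0.38 (stage 3) with the gametophyte. Between capsule stages it ran from 0.64 (stages 1 and 4) to 0.90 (stages 1 and 3). These are correlations across unigenes, which are not independent replicates. The first principal component of log2(RPKM + 1) held 54.9% of the variance and separated the gametophyte from the capsules. The second held 24.3% and placed stages 1 and 3 at 194.1 and 166.8 and stages 2, 4 and 5 at −83.1, −169.9 and −65.3.

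**Figure D3:**
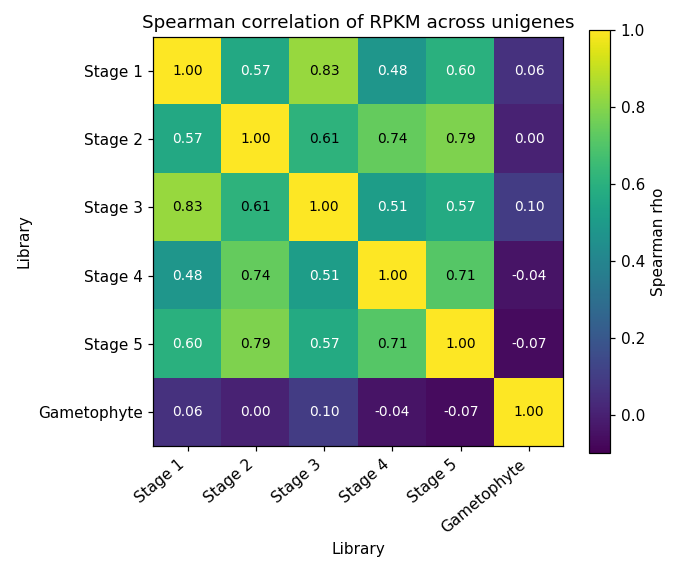
Spearman correlation of RPKM across 66294 unigenes between the 6 libraries, with rho printed in each cell. Stages 1 and 3 reach 0.83 and stages 2 and 5 reach 0.79, while the gametophyte lies between −0.07 and 0.10 with every capsule library.

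The same arrangement appeared in which unigenes were read at all. Of 24620 unigenes with at least 20 reads in one library, 13278 were read in all 6, 4283 in the gametophyte only, 1584 in every capsule library but not the gametophyte and 771 in stage 4 only. The next most frequent combinations were stages 2, 4 and 5 only, with 744 unigenes, and stages 1 and 3 with the gametophyte, with 627 unigenes. By contrast, 37 unigenes with 20 reads were read in stage 1 only, 3 in stage 2 only, 0 in stage 3 only and 18 in stage 5 only. The 3 of stage 2 are not named, since the rule fixed for these unnamed sequences allowed 4 identifiers.

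Contigs of one cluster, which share a cluster number in their identifier, were compared in the same way. In 1078 clusters with at least 20 reads in every library, the most read contig differed between stages 1 and 3 in 5.9% of clusters. It differed in 6.2% between stages 2 and 4, 6.0% between stages 2 and 5 and 6.7% between stages 4 and 5. It differed in 21.6%, 23.1% and 21.4% of clusters between stage 1 and stages 2, 4 and 5, and in 20.1%, 21.1% and 21.1% between stage 3 and stages 2, 4 and 5. Between the gametophyte and stages 1 and 3 it differed in 12.9% and 12.1%, and between the gametophyte and stages 2, 4 and 5 in 24.1%, 24.95% and 25.5%. In 101 of 1945 clusters one contig had at least 20 reads in stage 1 and none in stage 2 while another showed the reverse, where 100 shuffles of the cluster labels gave at most 47. Between the gametophyte and stages 1 and 3, 4 clusters each showed this, where shuffles gave 35 to 59 and 21 to 42. Between the gametophyte and stages 2, 4 and 5 the counts were 88, 89 and 86, where shuffles gave 84 to 129, 88 to 127 and 112 to 153. A count below the shuffles was thus also found for stage 5. Between stages 1 and 3 it could not occur, since 0 clusters had a contig read in stage 3 and not in stage 1 by this rule. For stages 2 and 4, 2 and 5, and 4 and 5 the shuffles also gave at most 1, so the count of 0 there carries no information.

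**Figure D4:**
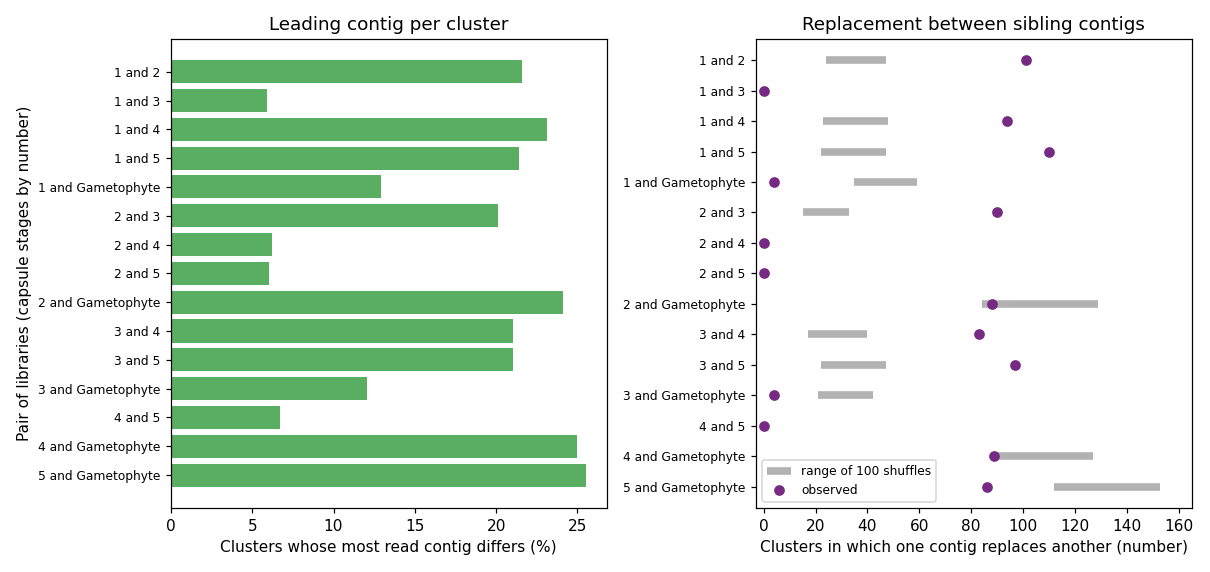
Left, percentage of 1078 clusters whose most read contig differs between 2 libraries; right, number of 1945 clusters in which one contig (20 or more reads) in the first library replaces another in the second (points), with the range of 100 shuffles of cluster labels (grey bars). The pairs 1 and 3, 2 and 4, 2 and 5, and 4 and 5 lie at 5.9% to 6.7% on the left; on the right they stand at 0, where the shuffles also gave at most 1.

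Consecutive stages were compared to follow the capsule through development. From stage 1 to stage 2, 10110 unigenes were higher and 12881 lower by at least 2-fold in RPKM + 1. From stage 2 to stage 3 the numbers were 10928 and 9236, from stage 3 to stage 4 they were 10573 and 13041, and from stage 4 to stage 5 they were 10201 and 6460. The share of unigenes changed was 58.3%, 53.4%, 60.9% and 45.9% for the 4 steps. With the 95% exact counting interval wholly beyond 2-fold, 4026 were higher and 5167 lower at the first step, 3839 and 3366 at the second, 5134 and 5104 at the third and 2879 and 2841 at the last. At the last step 61.2% of the changed unigenes were higher by the ratio, 53.6% after TMM scaling and 50.3% by the counting interval. The first 3 steps run between libraries whose leading contig differed in 20.1% to 21.6% of clusters, and the last step between libraries where it differed in 6.7%. No test was possible for single libraries.

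Few unigenes had values that moved one way at every step from stage 1 to stage 5. Of 46057 unigenes with a mean of at least 1 RPKM, 81 were higher at every successive stage with an overall difference of at least 4-fold and 11 were lower at every stage. After TMM scaling these numbers were 32 and 14. In a limma test of the slope per stage over 48293 unigenes, 0 rose and 0 fell at an adjusted p under 0.05, and 1301 (2.7%) had an unadjusted p under 0.05. Limma-voom on the recovered reads also called 0 in each direction, with 2819 at an unadjusted p under 0.05. With at least 1 read in every library and a mean of at least 5 RPKM, the values of 54 unigenes increased and those of 16 decreased at every step. By its counting bound, the first of the former was Unigene24847, of 2147 bases. It stood at 35.1, 40.5, 49.3, 74.5 and 293 RPKM in stages 1 to 5 and at 25.7 RPKM in the gametophyte. Its slope was 0.69 log2 units per stage with a standard error of 0.19 and a limma adjusted p of 0.858, and the slope was 0.35 without stage 5. The first of the latter was Unigene2597, of 4483 bases, at 26.8, 21.2, 19.5, 10.8 and 6.97 RPKM, with a slope of −0.45 (standard error 0.19, limma adjusted p of 0.858). The ratio of stage 5 to stage 1 was 8.35 for the former, with a 95% exact counting interval from 7.55 to 9.24, and 0.26 for the latter, from 0.219 to 0.307.

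Unigenes with a peak in one library, at least 2-fold above each of the other 5, were most frequent in the gametophyte, with 12411 of 46057 (26.9%). Among the capsules, stage 4 had 2534 such unigenes, stage 5 had 2412, stage 1 had 1882, stage 3 had 1305 and stage 2 had 902. At a 4-fold margin stage 4 stood further apart, with 1788 against 731 in stage 5, 629 in stage 1, 231 in stage 3 and 162 in stage 2.

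The capsules of different size were compared with the 3 small stages as the reference, so that the spread is that between stages 1, 2 and 3. In the big capsules of stage 5, 867 unigenes were higher and 2 lower than in the small capsules (limma, adjusted p under 0.05, 48293 tested), and in the middle-sized capsules of stage 4, 2156 were higher and 1 was lower. Of the higher calls, 833 in stage 5 and 1864 in stage 4 had no read in any small-capsule library. Among the 22311 unigenes read in every capsule library, limma called 0 in either direction in both comparisons, with 1626 at an unadjusted p under 0.05 for stage 5 and 923 for stage 4. Over all 48293, limma-voom called 0 in either direction for stage 5, with 4946 at an unadjusted p under 0.05, and 1642 higher and 14 lower for stage 4. Leaving out stage 2 raised the higher and lower calls to 5258 and 978 for stage 5 and to 6165 and 1494 for stage 4, whereas leaving out stage 1 or stage 3 gave 0 calls in both comparisons, and leaving out stage 4 gave 0 for stage 5. The 2 unigenes lower in stage 5 and the 1 lower in stage 4 are not named, for the reason given above.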

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

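The test of cluster membership in this part was chosen after the result was seen. For 7 measures of the 5 capsule libraries, which are different stages and not replicates, the gap of the highest or lowest library was set against the range of all 5. Chance singles out about 1 such group in 20. The stage 4 library had the lowest implied total, 5458335 reads, while the other 4 lay between 5729201 and 5752394. It also had the most unigenes of at least 2 RPKM that no other library contained, 1338, and the next capsule library (stage 5) had 310.

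The 1637 unigenes with any read in stage 4 alone had a median length of 256 bases, and those read in one other library alone had medians from 257.5 to 285 bases. The stage 4 set held 0.93% of the library. If contig clusters gather variant sequences, which is not given, variants of genes that other libraries also contained would be expected there. Yet 1.43% of the 771 with at least 20 reads lay in clusters (95% exact interval 0.714% to 2.54%), against 39.3% of other unigenes with as many reads (38.7% to 39.9%). Part of that gap follows length: among unigenes under 500 bases the shares were 0.458% (0.0946% to 1.33%) and 22.3% (21.1% to 23.4%). These sets were not matched further by length, with medians of 278 and 346 bases, and lengths of unigenes read in stage 4 alone can be underestimated. The shares speak against variants only if clusters gather them at such lengths, so variants are not excluded. Reads of another organism in that sample and genes used at stage 4 alone both stay open, as the sequences were not used here and stage 4 had 1 library.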

How the results depend on the processing

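For capsules against gametophyte, the higher and lower calls were 842 and 2424 with at least 50 reads in one library, 159 and 174 with reads in every library, and 938 and 82 with limma-voom, while a pseudocount of 0.1 gave 3957 higher calls. The split between directions turned under limma-voom, where all 938 higher calls had no gametophyte read. Lower calls with no read in any capsule library numbered 16646 in the main test and 2 with limma-voom, so most of the lower calls lost were of that kind. Why limma-voom did not call them was not tested. Leaving out single stages gave 1289 to 1567 higher and 18048 to 18301 lower calls. For big against small capsules, the higher and lower calls were 31 and 0 with at least 50 reads, and 0 and 0 with reads in every library and with limma-voom; without a filter 1533 were higher, and with a pseudocount of 0.1, 4 were lower. Leaving out single stages gave 0 to 5258 higher and 0 to 978 lower, with the highest counts without stage 2 and 0 without stage 1, 3 or 4. For middle against small capsules, 639 and 0 were called with at least 50 reads and 0 and 0 with reads in every library, and the lower calls were 0 with TMM scaling, 13 with a pseudocount of 0.1 and 14 with limma-voom. Leaving out single stages gave 0 to 6165 higher and 0 to 1494 lower, again with the highest counts without stage 2 and 0 without stage 1 or 3, and 0 lower without stage 5. Stages 1 and 3 resemble each other, so that the spread without stage 2 is that of the most similar pair. The stage slope gave 0 calls under every alternative run. The median number of unigenes higher in a stage than in the gametophyte was 5844 beyond 4-fold, 6902 with at least 5 RPKM, 5330 with the 95% and 4056 with the 99% counting interval; the median number lower was 14885, 13402 and 10382 under the last 3 of these. Between consecutive stages the medians in the same 4 settings were 3615.5, 4327, 3932.5 and 2954.5 higher and 3939, 4650, 4235 and 3153 lower. Unigenes in the gametophyte only numbered 4283 at 20 reads, 1945 at 50 reads and 3296 at 500 bases or more. Those in stage 4 only numbered 771, 271 and 118 in these settings, and those that met the minimum in each capsule library with no gametophyte read 168, 82 and 231, against 542 at 2 RPKM. Allowing 2 reads elsewhere gave 2253 for stage 4 and 990 for the capsules. With at least 10 RPKM in one library, rho was 0.94 for stages 1 and 3, 0.92 for stages 2 and 5, 0.81 for stages 1 and 2, and 0.23 for stage 3 and the gametophyte, whose Pearson r was 0.20 with a pseudocount of 0.1. With a mean of at least 5 RPKM, 2069 unigenes peaked in the gametophyte and a median of 413 in a capsule stage, 12 were higher at every stage and 0 lower; the stricter margins gave a median of 629, and 9 and 1. TMM scaling gave 32 higher at every stage. Detection at 5 reads gave 28003 unigenes in the gametophyte and a median of 19733 in the capsules, and unigenes of 500 bases or more gave 21713 and 21108. The other 74 summary values stayed within 1.5 times the reported value, or within 0.1 for a correlation. The medians over libraries were chosen as summaries after the data were seen; of the values for single libraries, 102 moved by more and 34 did not. Of the values for the named unigenes, 47 kept their direction and their side of the 0.05 threshold and 1 lost its call (CL3401.Contig3 with limma-voom); the slope of Unigene24847, which was not called, fell from 0.69 to 0.35 without stage 5. Restriction to reads in every library, limma-voom, counting intervals and the minimum of 20 reads were chosen after seeing the data. The edgeR fits planned for files with counts were not run because the files hold RPKM, and they were not run on the recovered reads either. Median-ratio scaling was applied within limma. No paired analysis was possible because each group had 1 library. Depth limits unigenes with few reads, for which a 2-fold ratio lies within counting error.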

Other observations

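The tests of explanations, the other orders of the stages and the other choices of a lone library were chosen after results had been seen. Of unigenes with at least 20 reads in one library, 294 were read in every library but stage 4, and 241 in stages 2, 3, 4 and 5 only. Stages 1 and 3 alone shared 180, and stages 4 and 5 alone shared 158. Ordering the capsule libraries as stages 1, 3, 5, 2 and 4 gave 922 unigenes that moved one way at every step by at least 4-fold, the highest of 60 orders and picked for that. The labelled order gave 92 and ranked 31 of 60, within a range from 18 to 922.

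The capsule libraries of stages 1 and 3 resembled each other more than either resembled stage 2. Unequal depth is argued against, because stages 1, 2 and 3 had nearly equal totals (5751812, 5752394 and 5747499 reads). At equal depth the rho of stages 1 and 3 still exceeded that of stages 1 and 2 by 0.25. Reads of gametophyte tissue in stages 1 and 3 stay open. No read in either was found for 333 unigenes of at least 100 RPKM in the gametophyte. However, 324 of these had no read in any capsule library and could come from another organism in the gametophyte material. By contrast, 627 unigenes of at least 20 reads were read in stages 1 and 3 and the gametophyte only. The leading contig differed from the gametophyte in 12.9% and 12.1% of clusters for stages 1 and 3, and in 24.1% to 25.5% for stages 2, 4 and 5. Source plants of different sequence types stay open: one contig replaced another between stages 1 and 2 in 101 clusters at 20 reads, against at most 47 in 100 shuffles, and the same count at the stricter minimum of 50 reads, which is no independent test, was 33 against at most 13. With contigs summed per cluster, rho exceeded the highest of 20 random sums in 4 of the 6 pairs of stage 1 or 3 with stage 2, 4 or 5. It did not for stages 1 and 2 (0.755, random 0.728 to 0.758) or 1 and 4. For stages 1 and 3 it fell from 0.924 to 0.894, below the random 0.924 to 0.940. The pairs 2 and 4, 2 and 5, and 4 and 5 also fell below their lowest random sums, at 0.919, 0.858 and 0.872 against 0.9391, 0.8987 and 0.9075. With stages 2, 4 and 5 the gametophyte exceeded its highest random sums, at 0.678, 0.648 and 0.584 against 0.6075, 0.5934 and 0.5655. With stages 1 and 3 the gametophyte lay within its random sums. Gene copies that switch between stages would give the same counts of replaced contigs. An exchange of the labels of stages 2 and 3 stays open too. The exchanged order ranked 7 of 60 by unadjusted calls of the slope. All orders with stages 1 and 3 together at one end ranked high, so this rank does not decide.

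The second pattern was the 4283 unigenes with at least 20 reads in the gametophyte and none in the capsules, where equal levels would leave practically none unread in the capsule libraries, which were deeper by the totals worked back. Among those of 500 bases or more, 23.1% (95% interval 21.5% to 24.7%) lay in contig clusters. In 6 comparisons matched by length or by length and reads, which overlap in their unigenes, 27.9% to 32.1% of other unigenes did. These shares speak against variants of capsule genes as the origin of all the longer ones only if clusters hold variants at least as often. That is not given and was not measured. Lengths of unigenes read in the gametophyte alone can also be underestimated. Under 500 bases the share was 23.0% against 18.3% to 24.3%. Variants stay open for the shorter ones and for at least a part of the longer ones. Of the 645 with a sibling contig, 80.9% had one read in the capsules. Shuffled labels gave 84.3% to 91.8%, too near saturation for the share to decide. A sibling also read in the gametophyte only was present for 42.6%, against at most 24.0% in shuffles, which another organism in the gametophyte material or genes used by the gametophyte alone could both give. The last 2 cannot be told apart without the sequences.

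The gametophyte set against the other 5 libraries gave 19989 calls, and the highest count for any other library set alone was 1791 (stage 4). No other of the 6 choices gave as many calls as the real one, but 6 choices are too few for a share under 0.05. For the stage slope, 39 of 60 orders of the stages gave at least the 1301 unadjusted calls of the labelled order, with a highest count of 11736, so chance is not excluded. The 12 orders with the highest counts all set stages 1 and 3 together at one end and gave several times the count of the labelled order. This points to a structure of the libraries that the labelled order does not follow. The order with stages 2 and 3 exchanged is one of these 12, as is every order with stages 1 and 3 together at one end. Its rank therefore does not decide on an exchange, and stage order under exchanged labels is not set aside.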
